A study of Strongylocentrotus droebachiensis with 6 samples.

How the data were processed

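Polyadenylated RNA was sequenced from embryos of the green sea urchin, Strongylocentrotus droebachiensis, at the mesenchyme blastula stage. There were 6 samples, 3 of intact control embryos and 3 of half-size embryos raised from separated blastomeres. The libraries came from a strand-specific kit, per the labels' protocols. The submitters' processing notes name Bowtie2 2.2.2, DESeq and edgeR, with no role for any of them. Per the file headers, gene identifiers follow the NCBI annotation of the Spur_4.2 assembly, which belongs to a related species, Strongylocentrotus purpuratus. Reads were therefore counted against another species' genes, and a gene whose sequence differs between the species may have lost reads in both groups alike. The counting program, strand setting and filters are not given in the sources used here. Reads from overlapping genes, antisense genes and near-identical copies can therefore not be separated.

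The table used here held 31261 rows, of which 30889 carried an identifier beginning with LOC and 372 a gene name. Of the named rows, 49 were transfer RNAs and 63 microRNAs. No gene-name table or genome was used, so rows with LOC identifiers have no name in the text. The 6 value columns hold a signal that the authors made by dividing gene read counts by a size factor per library. Each value was a whole multiple of its column's step, within 1e-06, for 100% of values, so the counts behind the deposited values could be recovered. The recovered totals ran from 1804336 to 2294541 reads per library. The same table holds the authors' mean signal, their log2 fold changes with standard errors, their test score (the fold change divided by its error) and their p-values and adjusted p-values, per the file headers. The model behind the authors' deposited comparison is not given in the sources used here.

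The headers repeat a single name for the 3 half-size columns and a single name for the 3 control columns. Columns could thus be assigned to groups but not to numbered replicates. The labels call the samples biological replicates and the half-size embryos siblings of the intact ones, and they do not say whether the replicates came from different parents. The p-values measure the spread between these samples.

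The planned test for read counts was edgeR's quasi-likelihood test. Because the file holds scaled values, the main test was limma-trend (limma 3.58.1, R 4.3.3) on log2(value + 1), over 18016 rows with a mean value of at least 1, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 differences are half-size minus control on this scale, which understates changes of weakly expressed genes. Count tests on the recovered reads (edgeR 4.0.16, limma-voom and DESeq2 1.42.0) were alternatives. Library measures were compared by two-sided exact permutation tests, for which 3 samples against 3 allow no p below 0.1.

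Deviations from the group means were then compared between columns, over 11129 rows with a mean of at least 10. Each half-size column correlated with 1 control column, at r = 0.76, 0.63 and 0.52, and every other correlation across the groups was at most 0.01. These 3 pairs are called A, B and C. The pairing comes from the values and was chosen after the data were examined. The labels neither state nor exclude it. Its source is not known. Because the libraries differ along it apart from their groups, fits with the pair as a block are printed beside the main test. Standard errors of log2 differences come from the blocked limma-trend fit, except those of the authors. For the genes named in the text the main test gave larger ones. They were 0.34 against 0.15 for dri, 0.56 against 0.14 for gcm and 0.84 against 0.13 for MTa. The pairing was the matching of half-size to control columns with the highest mean correlation (0.64, against 0.21 for the next). The blocked p-values treat it as known and take no account of this choice. The labels' replicate numbers could not be used for the pairing.

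Before the data were examined, 20 gene lists were fixed by symbol and product description. The data held no descriptions, so only symbols were matched, among 228 measured rows with a gene name. Measured members are those matched this way, and a short list does not mean that its other genes were absent. The 5 lists with at least 5 measured members were tested with camera (preset correlation 0.01, adjusted over 5 lists), and again with an estimated correlation and with fry. The other 15 lists are described by their members. The named genes were fixed by a rule with 3 parts. Part 1 took up to 8 rising and 8 falling genes past the main threshold with a mean CPM of at least 2 and no overlap between groups, and no gene met it. Part 2 took from each list up to 2 called genes, or the gene with the smallest p where none was called, and gave 17 genes. Part 3 always took the BMP1, BMP2/4, chordin, hatching enzyme, Alx1 and SM50 rows, and gave 6 genes. BMP1 counts under both. The genes hox1, CyI, Dlx and Ets4 were chosen after their values were seen, which makes 26 in all. Lists of homeobox, forkhead and aboral regulator genes in the closing section were collected after fold changes had been seen.

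The tests were tried on simulated counts for 11346 rows with 200 changed genes, in 10 simulations of the half-size against control comparison that included the pair structure. Without the pair in the model, limma-trend recovered 0.6% of 2-fold and 41.2% of 4-fold changes. With the pair as a block it recovered 54.8% and 91%, and 6.3% of its calls were false. edgeR recovered 0.4% and 39.1% without the block and 57.1% and 89.2% with it, with 7.8% false calls under the block. The simulated tests were given the true pairs, and the simulated spread came from the blocked fit, which favours the block. The real pairs were chosen from the values, a step that was not simulated. The shares of false calls therefore need not hold for the real blocked calls. Alternatives covered the tool, the scaling, the low-value filter, the pseudocount, the threshold, robust shrinkage and leaving out each library or pair. Figures were drawn with matplotlib 3.10.9.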

Results

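RNA sequencing compared intact sea urchin embryos with their half-size siblings. Fertilised eggs were held in aminotriazole (ATA) at 1 mM, which prevents hardening of the fertilisation envelope. At the 2-cell stage, 3.5 hours after fertilisation, embryos were washed for 15 min in seawater without calcium and magnesium and passed through a needle to separate the blastomeres. Control and half-size embryos were raised at 8 °C to the mesenchyme blastula, 46 hours after fertilisation, when skeletogenic cells enter the blastocoel. Each group had 3 samples. Read totals averaged 2104110 ± 262758 (SD, n = 3) in half-size and 2162300 ± 105818 (SD, n = 3) in control libraries (two-sided exact permutation p = 0.9, Benjamini-Hochberg p = 1 over 6 library measures; the smallest possible p is 0.1). The 100 most abundant rows took 27.1% ± 0.652 (SD, n = 3) of half-size and 26.7% ± 1.46 (SD, n = 3) of control reads.

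Differences between sample pairs exceeded those between half-size and control embryos. The first principal component held 49.2% of the variance and set pair A apart, and the second held 26.8% and parted pairs B and C. Of the sum of squares over 11129 rows, the pair took 74.9%, the group 9.0% and the rest 16.1%. Per degree of freedom these were 37.4%, 9.0% and 8.06%. MTa, a metallothionein gene, is a case with large differences between pairs and not a typical one. Its normalised read counts in half-size and control libraries were 24449 and 18270 in pair A, 2567 and 2333 in pair B, and 9427 and 10492 in pair C. Across genes, which are not independent replicates, half-size minus control differences correlated at r = 0.12 between pairs A and B, 0.03 between A and C and -0.01 between B and C.

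**Figure D1:**
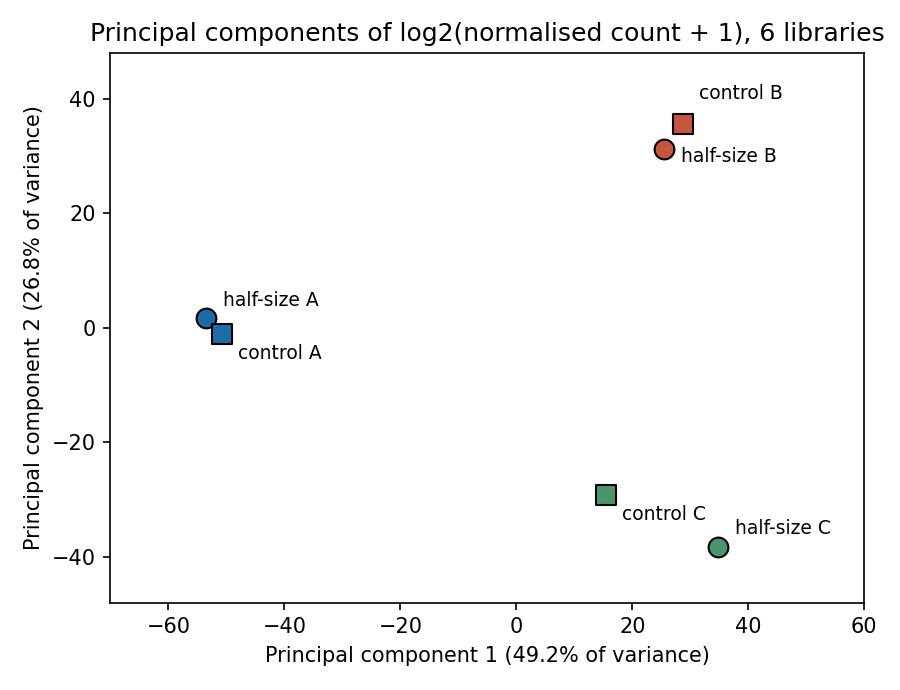
Each point is a library, placed by the first and second principal components of log2(normalised count + 1); circles are half-size libraries, squares are controls, and colours are the pairs found in the data. The components hold 49.2% and 26.8% of the variance, and libraries lie near their pair partner, not near their group.

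The comparison asked which transcripts differ in level when an embryo develops at reduced size. The homeobox gene hox1 had 60.3 ± 10.2 normalised read counts in half-size and 155 ± 26.9 in control embryos (SD, n = 3 each), a log2 difference of -1.35 ± 0.17 (SE with the pair as a block). The gene dri, an ARID-family transcription factor used in skeletogenic and oral ectoderm cells, had 107 ± 38.6 against 250 ± 94.5 (SD, n = 3 each), a log2 difference of -1.21 ± 0.15. Both were lower in the half-size library of each of the 3 pairs, between -1.13 and -1.47 for hox1 and between -1.05 and -1.37 for dri. NK2.1, a homeobox gene of the apical neuroectoderm, had 130 ± 67.7 against 254 ± 95.1 normalised counts (SD, n = 3 each). The cytoskeletal actin gene CyI had 641 ± 369 against 345 ± 165 (SD, n = 3 each), with log2 differences of 1.11, 1.02 and 0.49 in pairs A, B and C. hox1 and CyI were singled out after their values were seen.

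Without the pair in the model, limma-trend called 0 genes at adjusted p under 0.05, with 242 of 18016 rows (1.34%) at unadjusted p under 0.05. edgeR and limma-voom also called 0, with 129 and 118 of 11346 rows at unadjusted p under 0.05, and DESeq2 called 3 higher and 1 lower. With the pair as a block, limma-trend called 1 gene higher and 2 lower, edgeR 8 and 3, limma-voom 8 and 3, and DESeq2 15 and 7. All 3 limma-trend calls were among edgeR's 11, and all 11 of these among DESeq2's 22. hox1 and dri fell in these blocked fits (adjusted p = 0.0469 each in limma-trend and 0.0371 each in edgeR; 0.00139 and 0.000351 in DESeq2). NK2.1 fell and CyI rose in blocked DESeq2 alone (adjusted p = 0.0131 and 0.00397), and both missed the threshold in blocked edgeR (adjusted p = 0.0924 each). In fits without the block, NK2.1 went from -1.03 to -0.62 without the half-size library of pair A, and CyI from 0.87 to 0.44 without that library and to 0.41 without the control library of pair B. With 1 library left out the pairs are unbalanced, so differences between pairs enter these changes. The blocked limma-trend count was 0 without pair B, 80 without pair A and 31 without pair C. It was also 0 with a pseudocount of 0.1 or with no low-value filter. Under every other matching of half-size to control columns, blocked limma-trend and blocked edgeR both called 0 genes. The matching used was chosen for its high correlation, which leaves little spread within the block and so favours calls. This contrast therefore lends no weight to the pairs or to the calls.

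All other calls of blocked limma-trend, edgeR and DESeq2 were rows that the file does not pair with gene names. LOC579269 rose from 105 ± 8.36 in controls to 250 ± 12.1 normalised counts (SD, n = 3 each), a log2 difference of 1.25 ± 0.14 (SE; adjusted p = 0.0469 in blocked limma-trend). LOC593467 rose from 190 ± 89.8 to 790 ± 245 (SD, n = 3 each; adjusted p = 0.0473 in blocked edgeR, 0.0690 in blocked limma-trend). LOC588806 was lower, with 915 ± 804 in half-size and 1747 ± 1061 in control libraries (SD, n = 3 each; adjusted p = 0.0473 in blocked edgeR, 0.0694 in blocked limma-trend). Groups did not overlap in 509 of 11129 rows (4.57%). Chance gives 10% for libraries with no pair structure, and the other 3 ways of exchanging libraries within pairs gave 3.40% to 4.83%. All 3 pairs had the same direction in 2937 rows (26.4%, where chance gives 25%), against 2436 to 3125 rows in those 3 exchanges.

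Of the rows used here, the authors' deposited table had 4 at adjusted p under 0.05, 3 higher and hox1 lower. For hox1 the authors' deposited table gave a log2 fold change of -1.36 (SE 0.30) and an adjusted p of 0.0274. DESeq2 without a pair term, run on the recovered reads, called the same 4 rows, with fold changes within 0.000384 of the deposited ones. Of these 4, main limma-trend called 0, blocked limma-trend 2 and blocked edgeR 4.

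**Figure D2:**
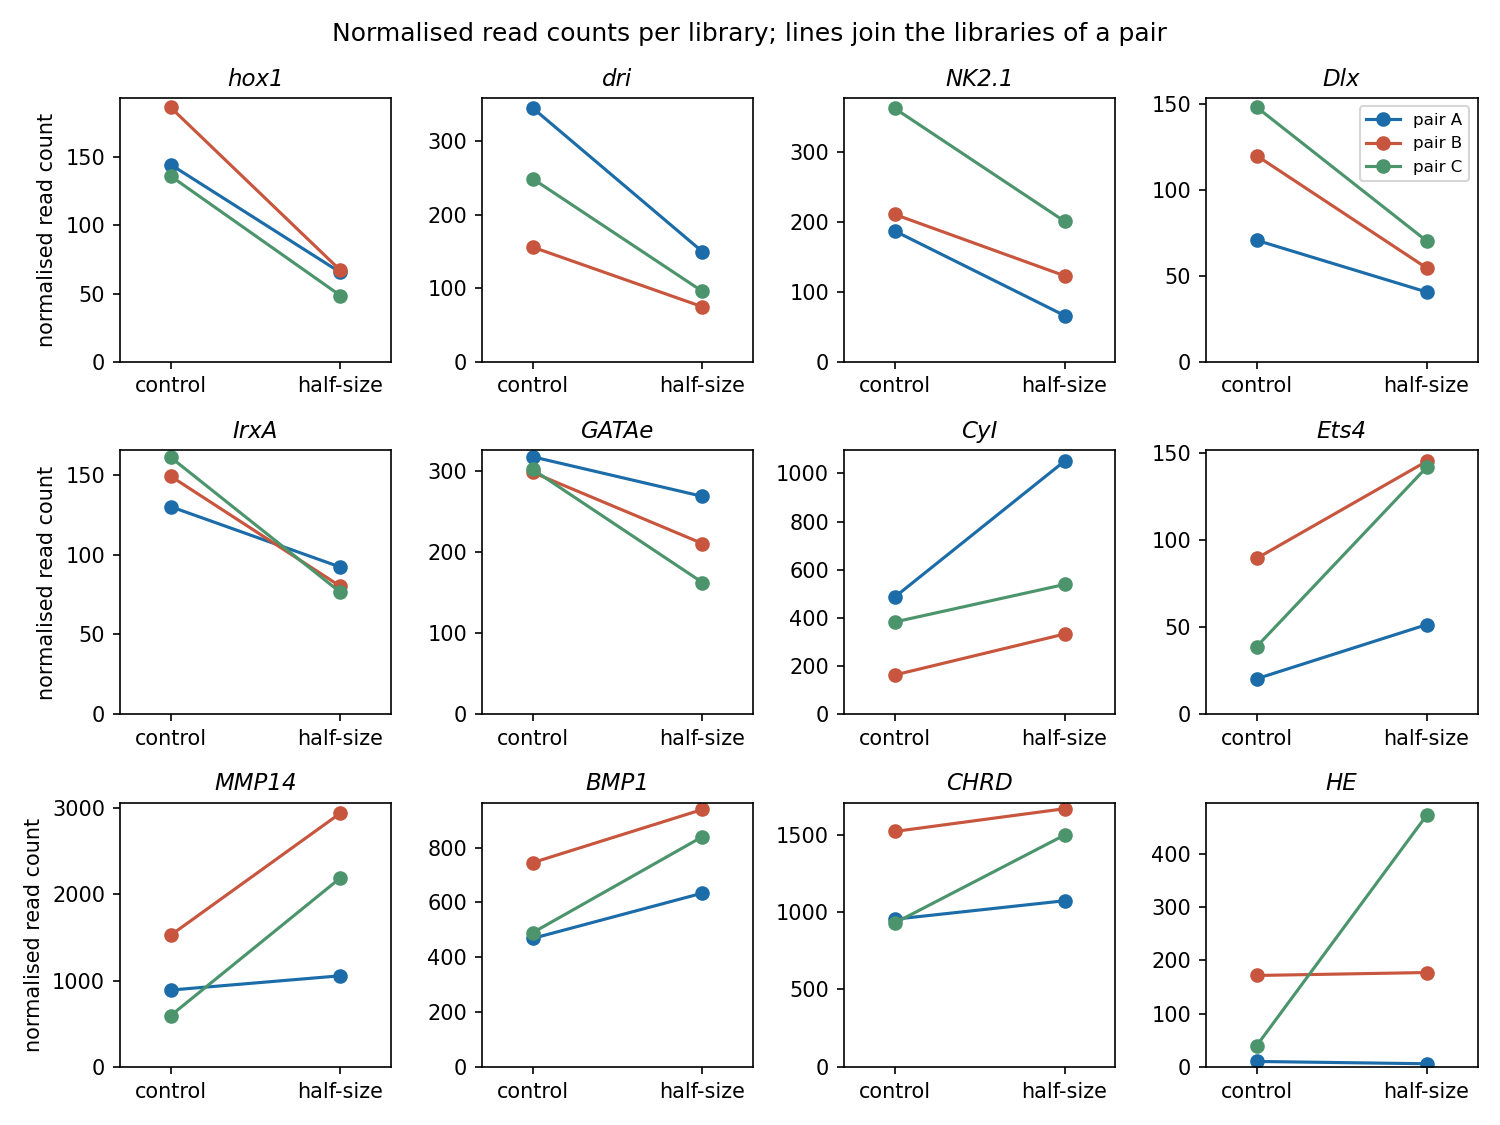
Normalised read counts of 12 genes in control and half-size libraries, with a line joining the libraries of each pair and a vertical axis from 0 in each panel. Lines fall in all 3 pairs for hox1 and dri, while HE, the hatching enzyme gene, goes up steeply in pair C alone.

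Genes of dorsoventral ectoderm patterning had lower values in half-size embryos for 8 of 10 measured members, with a median log2 difference of -0.22. Chordin was planned for this list, but its row is named CHRD and was not matched, so these counts leave it out. It went the other way, with log2 differences of 0.17, 0.13 and 0.69 in pairs A, B and C. IrxA, an Iroquois homeobox gene of aboral ectoderm, had 82.9 ± 8.24 against 147 ± 15.6 normalised counts (SD, n = 3 each), a log2 difference of -0.81 ± 0.17 (SE with the pair as a block). Dlx, a distal-less homeobox gene, had 55.2 ± 14.8 against 113 ± 39.1 (SD, n = 3 each) and a log2 difference of -0.99 ± 0.18, and was singled out after its value was seen. NK2.2 differed by -0.46 ± 0.12. These 3 genes lay lower in every pair, while Not and FoxG differed by 0.04 and 0.02. For BMP2/4, a secreted ligand of dorsoventral patterning, the counts were 214 ± 30.2 and 225 ± 9.48 (SD, n = 3 each). No member passed over all genes. Adjusted over the list alone, limma-trend called IrxA without the block and IrxA, Dlx and NK2.2 with it. By camera the list stood lower than other genes (adjusted p = 8.21e-05; 2.39e-05 with the block). The call was lost with an estimated correlation (adjusted p = 0.318 with an estimated correlation; 0.427 with the block). Fry, which asks whether the members move one way and compares them with no other genes, gave adjusted p = 0.386, and 0.201 with the block.

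**Figure D3:**
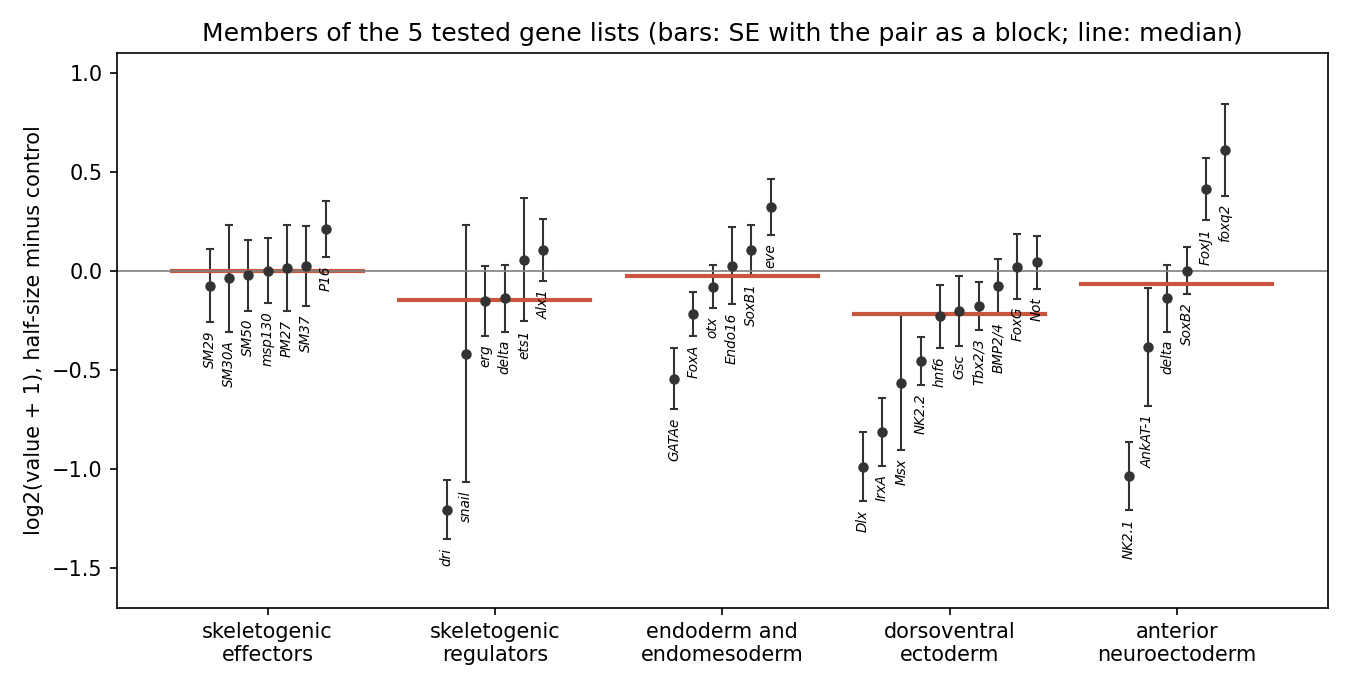
Log2 differences (half-size minus control) of the members of the 5 tested gene lists; points are genes, bars are standard errors with the pair as a block, and red lines are list medians. The dorsoventral median lies at -0.22 and the skeletogenic effector median at 0.00155.

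Skeletogenic effector genes, which encode spicule matrix and cell surface proteins of the skeleton-forming cells, gave a median log2 difference of 0.00155 over 7 members. Of these, 0 passed over all genes or adjusted over the list alone. The median hid opposite differences between pairs. All 7 members were higher in the half-size library in pair A (0.46 to 0.87) and lower in pair C (-0.13 to -0.73). The spicule matrix gene SM50 had 713 ± 572 normalised counts in half-size and 632 ± 271 in control embryos (SD, n = 3 each), with pair differences of 0.56, -0.13 and -0.49. Its sign turned in edgeR (0.17) and DESeq2 (0.18) without the block, and not in limma-voom or in either tool with the block. P16 differed by 0.21 ± 0.14 (SE with the pair as a block). Camera gave adjusted p = 0.857 for these effectors; without the half-size library of pair A the direction turned to lower (adjusted p = 2.16e-05; adjusted p = 0.313 with an estimated correlation), and without both libraries of pair A likewise (adjusted p = 0.00644; 0.409 with an estimated correlation). The first of these keeps the control library of pair A, where SM50 had 931 normalised counts against 403 and 560 in the other controls, so a difference between pairs enters it. Of 6 measured skeletogenic regulators, 4 had lower values and dri alone passed adjusted over the list alone, with and without the block. Alx1, a homeobox regulator of skeletogenic fate, had 366 ± 188 against 329 ± 123 (SD, n = 3 each). For the regulators camera gave adjusted p = 0.121, which became 0.00148 without the half-size library of pair A and 0.00644 without both libraries of pair A. With an estimated correlation these adjusted p-values were 0.194 and 0.244.

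Endoderm and endomesoderm regulators were split, with 3 of 6 lower (camera adjusted p = 0.655). GATAe, an endoderm transcription factor gene, had 214 ± 53.1 against 306 ± 10.2 normalised counts (SD, n = 3 each), a log2 difference of -0.54 ± 0.16 (SE with the pair as a block). It passed adjusted over the list alone with the block. In the non-skeletogenic mesoderm list, all 3 measured members had negative differences. gcm, a pigment cell regulator, had a log2 difference of -0.53 ± 0.14 (SE with the pair as a block, 0.56 in the main test). It passed adjusted over the list alone with the block, and not without it. Left-out single libraries, in fits without the block, moved gcm to -0.00207 (half-size of pair C), -0.15 (control of B), -0.26 (control of A), -0.81 (half-size of B) and -1.18 (control of C). Leaving out 1 library unbalances the pairs, so differences between pairs enter these values. Within pairs A, B and C, gcm differed by -0.59, -0.72 and -0.28. GATAe became -0.36 without the half-size library of pair C. Of 6 anterior neuroectoderm genes, 3 had lower values (camera adjusted p = 0.857). With the block, NK2.1 (-1.03 ± 0.17), FoxJ1 (0.41 ± 0.16) and foxq2 (0.61 ± 0.23) passed adjusted over the list alone, in opposite directions. FoxJ1, a regulator of motile cilia, was also the 1 measured gene of the cilia list, where its blocked p of 0.0248 in limma-trend needed no adjustment. In that fit 5.27% of all rows had an unadjusted p under 0.05. Adjusted p over all genes in blocked limma-trend was 0.936 for FoxJ1 and foxq2, 0.660 for GATAe, 0.587 for gcm and 0.121 for NK2.1. Passes over a list alone were not corrected for the number of lists. Without pair C FoxJ1 differed by 0.25, and without the half-size library of pair A NK2.1 differed by -0.62.

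Among 4 measured protease genes, BMP1 and MMP14 had higher values in the half-size library of every pair, and HE and MMP16 did not. BMP1, a tolloid-type metalloprotease, had 804 ± 156 against 568 ± 154 normalised counts (SD, n = 3 each), a log2 difference of 0.52 ± 0.13 (SE with the pair as a block). The matrix metalloprotease gene MMP14 had 2064 ± 950 against 1004 ± 477 (SD, n = 3 each) and log2 differences of 0.25, 0.95 and 1.88 in pairs A, B and C (1.02 over all, 0.60 without pair C). Both passed adjusted over the list alone with the block, in lists of 2 genes that were not tested as sets, and neither passed over all genes (blocked limma-trend adjusted p = 0.521 and 0.427). MMP16, named after its values were seen, differed by 0.25 ± 0.25, with -0.49 in pair C. HE, the hatching enzyme gene, had 218 ± 235 against 73.9 ± 85.8 (SD, n = 3 each). Its half-size and control counts were 471 and 39.96 in pair C, 177 and 171 in pair B and 5.94 and 10.2 in pair A, and its log2 difference of 0.96 became -0.32 without pair C. Chordin (CHRD), an extracellular BMP antagonist, had 1412 ± 306 against 1134 ± 334 (SD, n = 3 each), a log2 difference of 0.33 ± 0.14. Ets4, an ETS-family transcription factor gene singled out after its value was seen, had 113 ± 53.1 against 49.7 ± 35.8 (SD, n = 3 each; blocked DESeq2 adjusted p = 0.0696).

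The remaining lists had 4 or fewer measured members, and none of their genes passed over all genes or adjusted over the list alone. In the Wnt and FGF list, Wnt8 and wnt1 differed by 0.22 ± 0.13 and 0.12 ± 0.18 (SE with the pair as a block). The 4 measured aboral ectoderm effectors had a median of 0.01, and ARS, an arylsulfatase gene, had 2.64 ± 2.02 against 4.12 ± 0.976 normalised counts (SD, n = 3 each). The 3 cytosolic ribosomal protein genes had a median of 0.05, with 0.18 ± 0.13 for rps15a. Single measured genes were ebr1 of the hyaline and apical matrix list (0.10 ± 0.12), SPARC of the basement membrane list (-0.00150 ± 0.11), MTa of the stress list (0.13 ± 0.13), Cdc6 of the cell cycle list (0.05 ± 0.20) and atm of the DNA damage list (0.13 ± 0.42). No histone gene of that list reached the mean of 1, and no row was matched for the mitochondrially encoded or the hypoxia and glycolysis lists.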

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

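The pair block, its leave-outs, leave-outs with an estimated correlation, edgeR with TMM, rescaled limma-trend and added synonyms were chosen after the data were examined. No block on the labels' replicate numbers could be fitted, because the columns carry none; the replicate block used here rests on pairs found from the values. The count of 0 called genes (limma-trend, 242 at unadjusted p under 0.05) stayed at 0 in edgeR and limma-voom, under every scaling, filter, pseudocount, threshold and shrinkage tried, and without each library or pair (range 0 to 0). It became 4 in DESeq2 and, with the replicate block, 3 in limma-trend, 11 in edgeR and 22 in DESeq2. The blocked count of 3 was 8 with a pseudocount of 5, 0 with a pseudocount of 0.1, 0 with no filter, 10 with a stricter filter, and between 0 (without pair B) and 80 (without pair A) when a pair was left out; the cause was not tested. TMM and total count scaling left it at 3. Of the 26 named genes, 15 kept their sign in up to 25 settings, and 589 of 637 values kept both direction and side of the threshold. Among the 15, gcm ran from -1.18 to -0.00207 over unblocked leave-outs of 1 library, which differences between pairs enter. With the block dri (-1.21 in limma-trend, -1.22 in edgeR, -1.21 in DESeq2) and hox1 (-1.35, -1.37 and -1.37) passed, hox1 also in DESeq2 without it (-1.36), and in blocked DESeq2 NK2.1 (-1.02) and CyI (0.88). SM50 turned positive in DESeq2 (0.18) and in edgeR with TMM (0.17), size factors (0.18), upper quartile (0.16) and total counts (0.13). SPARC turned positive in DESeq2 (0.00477) and in edgeR with size factors (0.00268), and Cdc6 negative in edgeR with total counts (-0.0138). The cause was not tested, and each lies within its standard error of 0.

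Over leave-outs of a library or a pair, log2 differences ran from -0.21 to 0.50 for P16, -0.0171 to 0.42 for Wnt8, -0.0379 to 0.34 for ebr1, -0.20 to 0.23 for SPARC, -0.72 to 0.99 for MTa, -0.27 to 0.35 for Cdc6, -0.0367 to 0.37 for atm, -0.19 to 0.00907 for BMP2/4, -0.32 to 2.75 for HE, -0.29 to 0.38 for Alx1 and -0.64 to 0.32 for SM50. Among uncalled genes that kept their sign, they ran from 0.15 to 0.56 for CHRD, 0.0390 to 0.32 for rps15a, -1.19 to -0.20 for ARS and 0.78 to 1.82 for Ets4. These fits had no block, and leaving out 1 library unbalances the pairs. The ranges therefore also hold differences between pairs.

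The dorsoventral list kept camera's call under total count scaling, with synonyms, with the block and without each library or pair (adjusted p from 1.23e-06 to 0.0407), and lost it with an estimated correlation (0.318; 0.427 with the block; 0.321 without the half-size library of pair A and 0.232 without pair A). Fry, a test of another question, did not pass (0.386; 0.201 with the block). The count of lists past the threshold, 1 in the main test, was 0 with an estimated correlation and by fry, with or without the block, and from 1 to 3 over leave-outs with the preset correlation, with 3 without the half-size library of pair A or without pair A, both 0 with an estimated correlation. Adjusted p over leave-outs ran from 2.16e-05 to 0.947 for the skeletogenic effectors, which turned lower without the half-size library of pair A, without pair A and without the control library of pair B, and from 0.00148 to 0.752 for the skeletogenic regulators. It ran from 0.121 to 0.979 for the endoderm list, which turned higher without the half-size library of pair C, and from 0.225 to 0.998 for the anterior neuroectoderm list, which turned higher without the half-size library of pair A or the control library of pair C and with synonyms added (0.929). The block on the labels' replicate numbers, summing of rows of the same name (each name had 1 row) and matching by product description were not run. At 1804336 to 2294541 reads per library, genes with few reads limit every count above.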

Other observations

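Of the tests in this part, the homeobox and forkhead lists, the comparison of aboral genes, the matched random lists, the 20 further thinning draws and the splits of the main test were chosen after results had been seen; the other tests were set before theirs. Among 18 homeobox transcription factor genes measured under a gene name, 14 had lower values in half-size embryos, 10 of them in all 3 pairs. The median log2 difference of the class was -0.35. Homeobox genes among the rows with LOC identifiers were not counted. IrxA, Dlx, NK2.2, hnf6, Msx, Gsc and Not are also in the dorsoventral list, so the camera results of both lists rest in part on the same genes. Besides hox1, NK2.1, Dlx and IrxA, lower values were measured for Nk1 (-0.70 ± 0.21, SE with the pair as a block), HMX (-0.45 ± 0.14) and NK2.2 (-0.46 ± 0.12), while eve (0.32 ± 0.14) and Lim1 (0.20 ± 0.18) had higher ones. With the pair as a block, camera placed the class below other genes (unadjusted p = 7.23e-10), which did not pass with an estimated correlation (p = 0.0579 with an estimated correlation). Of 7 forkhead genes 5 had higher values, with a median of 0.02 (blocked camera p = 0.0468; p = 0.258 with an estimated correlation). The largest of these differences was in foxx, with 71.1 ± 36.7 against 31.6 ± 20.7 normalised counts (SD, n = 3 each).

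Low expression of the class, with shared noise at low counts, stays open as a source of the homeobox pattern. Among 10000 lists of other rows matched on mean expression, 0% had as low a median, but the class was collected after low members had been seen and random rows share no noise, so this excludes nothing. A smaller share of aboral ectoderm cells, for the aboral members, would lower aboral effector genes too. The 3 effectors with a mean of at least 10 had a median of 0.16 (-0.13 to 0.21). The 4 aboral regulators had a median of -0.69 (-0.99 to -0.18). The effectors thus showed no joint fall, although SPEC1 and spec2c lay above 0 mainly through pair A (0.56 and 0.57). ARS (-0.61) was left out for its few reads. The comparison cannot decide the question, because the regulators were collected after fold changes had been seen and the effectors are few. A joint fall of the class stays open as a hypothesis. Without the 4 members of smallest p, blocked camera gave p = 0.000923, and p = 0.165 with an estimated correlation; the demand that both pass was added after the first value was seen.

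The pairing of libraries held after every library was thinned to the smallest total (lowest within-pair r = 0.51) and without the 1000 most abundant rows (lowest r = 0.52), so neither depth nor a few abundant rows accounts for it. Parents shared within a pair, with sequence differences from the reference, may account for the pairing and stay open. In 5 rows both libraries of a pair were at 0 with all 4 others above 20, against 0 rows for libraries of different pairs, too few to decide. A shared day of culture or of library preparation was not tested, and the labels give none.

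The half-size minus control differences did not follow the axes that separate the pairs with a common sign in all pairs. Correlations in pairs A, B and C were -0.05, -0.06 and 0.24 on the first axis and -0.05, 0.07 and 0.09 on the second. This argues against a shift in the same direction along those axes in every pair. Shifts that differ in direction between pairs, and a difference in developmental stage along another axis, stay open and untested. To examine library depth, every library was thinned to 1 total, and the differences of the 22 genes called by blocked DESeq2 were measured again. Their median size after thinning was 1.06 times that before, and 1.01 to 1.05 times in 20 further draws. This cannot decide on depth. The values were scaled per library before and after, and these genes had mean values of at least 63.3, so little shrinkage was possible. Read totals averaged 2104110 in half-size and 2162300 in control libraries. Separation of the blastomeres and reduced size went together in the half-size samples, and no test here separates their effects.

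The 6 libraries can be split in 10 ways, too few for a share under 0.05. The real split gave 0 calls, a count that all 10 reach by construction, and the highest other gave 8. The 6 splits that kept 2 pairs whole gave 878 to 2569 rows at unadjusted p under 0.05, and the 4 that parted all 3 pairs gave 117 to 242, which points to the pair structure. Of those 6, 1 made calls. For lists past the threshold the real split gave 1, 7 of the 10 splits gave as many, and the highest other gave 2. Within pairs there are 4 assignments, also too few. The real one alone (1 of 4) reached its 3 blocked limma-trend calls, with 0 in the highest other. At unadjusted p under 0.05 the real assignment gave 950 rows, and another gave 964.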
